A study of Mus musculus with 8 samples.

How the data were processed

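Total RNA from mouse C2C12 myoblasts was sequenced in 8 libraries, 4 from cells with a non-targeting shRNA and 4 from cells with an shRNA against Atad2. Per the labels' protocols, cells were lysed with QIAzol 48 h after transfection, RNA was purified with the PureLink kit, and cDNA was made with NEBNext kits whose second-strand step keeps strand. Libraries were sequenced on an Illumina NovaSeq. Per the submitters' processing notes, bcl2fastq 2.20, SAMtools 1.1, HTSeq 0.13.5 and DESeq2 (version not given) were used with the mouse genome build mm10. The order of these tools is not given. The aligner, the annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap or share reads with near-identical copies are uncertain.

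The deposited table held 35976 genes by symbol in 8 columns. As the authors deposited them, the values were log2(x + 1) of read counts divided by a size factor per library, rounded to 3 decimals. This form was read from the values: the low values of each library, once converted back, lay on whole multiples of a single step, within a tolerance of 0.1 reads for 100% of them. Reads were recovered with that step, rounded to whole numbers, and used for depth, read ranges and floors. Only low values were checked in this way, and rounding to 3 decimals leaves high read counts approximate. The floor was 3 reads of a library's total. Genes were matched by symbol to RefSeq coordinates on GRCm38, the assembly that mm10 names, and 33506 genes matched.

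Genes with a mean above 3 on the log2 scale were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), without covariates. Tests were two-sided with a Benjamini-Hochberg adjusted p under 0.05. The 33 gene lists with at least 3 measured members, 7 of them cell type markers, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Of 1127 list symbols, 1096 were in the table, 25 of them under an older symbol. Mitochondrially encoded transcripts were not found under their symbols and are not analysed here. Single values were compared by exact two-sided permutation tests over the 35 splits of the 8 libraries, with tables made in Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 and plots in matplotlib 3.10.9.

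The test, filter, lists, alternatives up to fry and the rule for naming genes were chosen before the data were examined. The rule names Atad2, Atad2b and 10 fixed genes of myogenesis and autophagy. It adds the 10 largest changes in each direction with a mean of at least 5 and no overlap between groups, passing over predicted genes without a proper symbol (3 higher, 0 lower). For each list described it adds up to 4 changed members in the main direction and 2 in the other, by adjusted p. Some genes that this rule names are not reported here. The alternatives were no filter, a mean above 5, an offset of 8 in place of 1, median centring, quantile normalization, eBayes without trend or with a robust prior, library weights, the replicate block, leaving out each library, an adjusted p under 0.01 and a 2-fold minimum. Cyclic loess, limma-voom on the recovered reads and thinning to 50.3 Mreads per library were chosen after seeing the data, as was a list of 25 NRF2 targets.

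The procedure was tested on data simulated for this comparison with 15110 genes tested. Of 50 genes changed by 0.25 on the log2 scale 72% were recovered, of 50 changed by 0.5 96%, and of 50 each changed by 1 or 2 100%. All these genes had a mean above 50 reads, and every gene had the same simulated dispersion, so recovery of weaker genes was not tested. Far fewer genes were changed than were called in the real comparison, and no shift with expression level was simulated. Of 224 genes called in the simulation, 2.23% were unchanged, and 0 of 20 unchanged lists passed limma's camera at an adjusted p under 0.05. Genes were simulated independently of each other, while the estimated correlation within the real lists reached 0.628 (ribosomal proteins). False calls by camera in lists of correlated genes were therefore not tested.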

Results

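RNA was sequenced in 8 libraries from C2C12 cells, a mouse myoblast line that proliferates as single cells and can be induced to fuse into myotubes. In 4 libraries the cells had received a non-targeting control shRNA, and in the other 4 an shRNA against Atad2, which encodes a chromatin ATPase with a bromodomain that binds acetylated histones. RNA was taken 48 h after transfection. The recovered depth was 61.4 to 73.0 Mreads (M for the prefix mega) per library in the control group and 50.3 to 72.3 Mreads in the Atad2 group, a difference within the spread between replicates (66.6 ± 4.80 against 61.7 ± 10.4 Mreads, SD, n = 4 each, exact permutation p = 0.457). At these depths, a gene without reads in a library lay below 0.0411 to 0.0596 RPM (3 reads of the library total), a floor that covers counting error only. Levels are given as log2(normalized count + 1), as mean ± SD over 4 libraries, and log2 fold changes as Atad2 over control shRNA ± SE. A fold change on this scale understates the change of weakly expressed genes. The labels do not say whether the 4 libraries of a group came from separate cultures or transfections, so p-values measure only the spread between these libraries.

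The knockdown target was lower in every library that received the Atad2 shRNA. Atad2 (chromosome 15, 58094044 to 58135525, GRCm38, protein-coding) lay at 14.66, 14.74, 14.67 and 14.60 in the control libraries and at 11.87, 11.77, 12.05 and 12.05 in the Atad2 libraries. Its log2 fold change was -2.73 ± 0.05, which made it 6.66-fold lower than in the controls, with 27186 to 29381 reads per control library and 3306 to 4086 per Atad2 library (limma adjusted p = 4.6e-20). The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries can give. Its paralog Atad2b stood at 11.42 ± 0.07 in the controls and 11.55 ± 0.07 in the Atad2 libraries, with overlapping values. The Atad2b difference of 0.12 ± 0.05 passed the threshold (limma adjusted p = 0.027), but that call was lost under 7 of 20 alternatives (limma adjusted p from 0.00765 to 0.285). Among them were leaving out control replicate 1 (0.101), control replicate 2 (0.0694), Atad2 replicate 2 (0.056) and Atad2 replicate 3 (0.101).

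**Figure D1:**
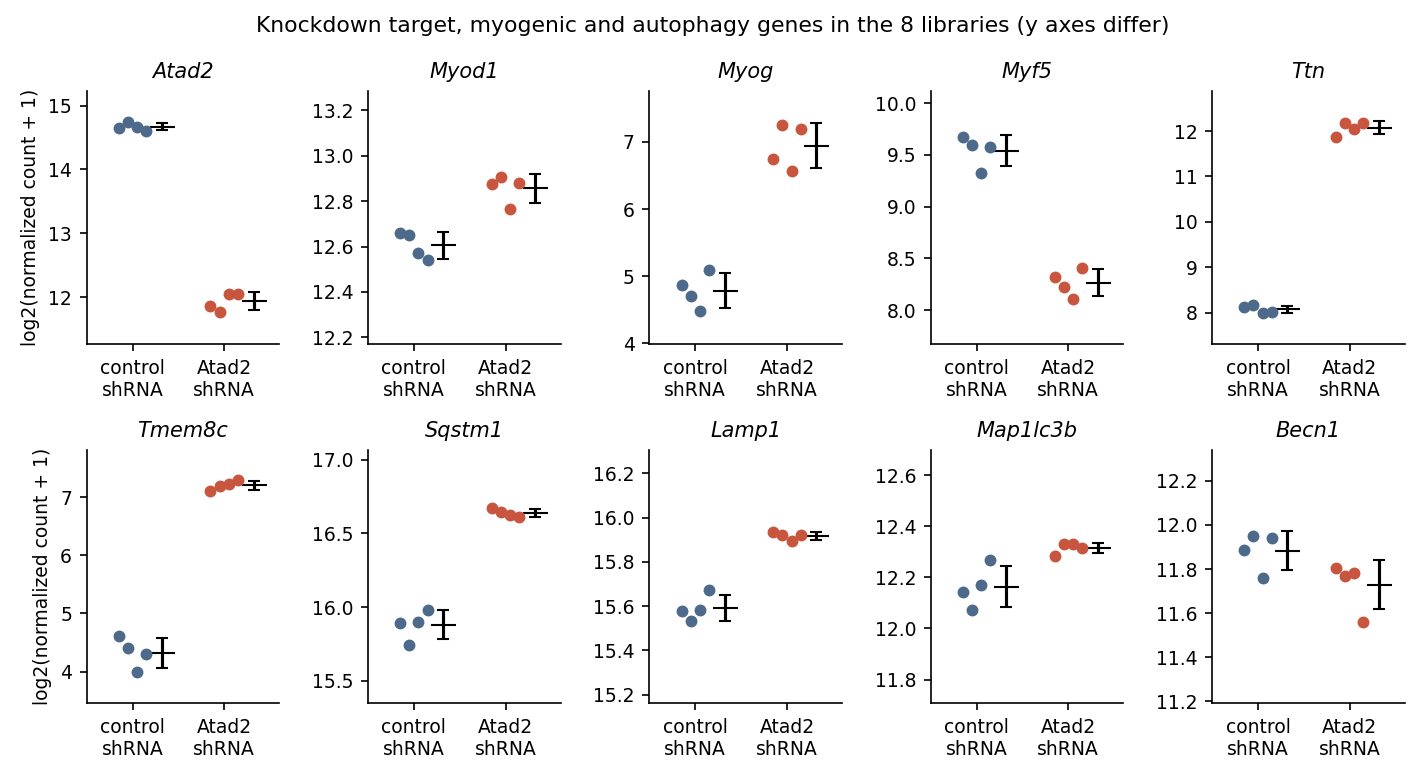
Level of 10 genes in each of the 8 libraries, as log2(normalized count + 1), with points for single libraries and the mean ± SD of 4 beside them (the y axes differ between panels). Atad2 fell from 14.67 to 11.93, Myog, Ttn and Tmem8c rose by more than 2 log2 units, and the 2 groups overlapped for Becn1.

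Of 14703 genes tested between the Atad2 and control libraries, 4528 were higher and 4352 lower in the Atad2 libraries, and 5823 did not pass the threshold (limma, adjusted p under 0.05). At least a 2-fold change was seen for 370 of the higher and 1265 of the lower genes, and at least a 4-fold change for 122 and 325. The 4 values of one group did not overlap those of the other for 53.5% of genes, against 2.86% by chance. The first principal component held 65.1% of the variance and separated the groups. Atad2 replicate 3 stood apart from the other 7 libraries on the second, which held 8.29%. Without that library, 4391 genes were higher and 4206 lower.

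The 10 largest increases are given for genes with a mean log2 level of at least 5 and no overlap between the groups. Clec4d, a C-type lectin receptor, rose from 3.26 ± 0.62 to 9.08 ± 0.23 (log2 fold change 5.82 ± 0.27, limma adjusted p = 1.7e-13). Slpi, a secreted inhibitor of leukocyte proteases, rose from 6.02 ± 0.48 to 11.46 ± 0.07 (5.44 ± 0.16). The somatostatin receptor gene Sstr2 rose by 4.41 ± 0.32, the growth factor gene Igf2 by 4.00 ± 0.13 and Ttn, which encodes the giant sarcomere protein titin, by 4.00 ± 0.07. Tmprss11b (a serine protease), Postn (the matrix protein periostin), Gsta2 (a glutathione transferase), Slc7a11 (the cystine and glutamate exchanger) and Siglec15 (a sialic acid-binding lectin) rose by 3.25 to 3.96. Gsta2 belongs to a family of near-identical copies, so its own share of these reads is uncertain. Limma adjusted p-values of these 10 genes were at most 4.2e-09.

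The 10 largest decreases are given for genes with the same minimum mean level and no overlap, since weaker genes can show larger changes. Dkk3, a secreted protein of the Dickkopf family, fell from 497 to 612 reads per control library to 1 to 5 per Atad2 library (log2 fold change -7.08 ± 0.35, limma adjusted p = 3.6e-13). Rorb, a nuclear receptor gene, fell from 9.20 ± 0.25 to 3.73 ± 0.62 (-5.47 ± 0.26). Tpsab1, a tryptase gene that the matched annotation lists as a transcribed pseudogene, changed by -4.97 ± 0.13, the organic anion transporter gene Slco4a1 by -4.78 ± 0.20, and Msln, which encodes mesothelin, by -4.67 ± 0.12. Pdgfd, F5 (coagulation factor V), Parm1, Lgalsl and Tnfsf15 fell with log2 fold changes from -4.57 to -4.17. Limma adjusted p-values of these 10 genes were at most 7e-10.

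The direction of the calls depended on how strongly a gene was expressed. Among genes with a mean log2 level of 3 to 5, 105 were higher and 522 lower in the Atad2 libraries, with a median log2 fold change of -0.56. Among the 1717 genes above 13, 992 were higher and 346 lower, with a median of 0.11. At 11 to 13, 2089 of 4452 genes were higher and 994 lower. Counts of higher members in the lists of strongly expressed genes below are to be read beside these shares. The number of genes with any read was 18889 ± 38.7 in the control libraries and 17753 ± 153 in the Atad2 libraries (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible). For genes at 10 reads or more the numbers were 15022 ± 70.0 and 14196 ± 145 (exact permutation p = 0.0286).

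**Figure D2:**
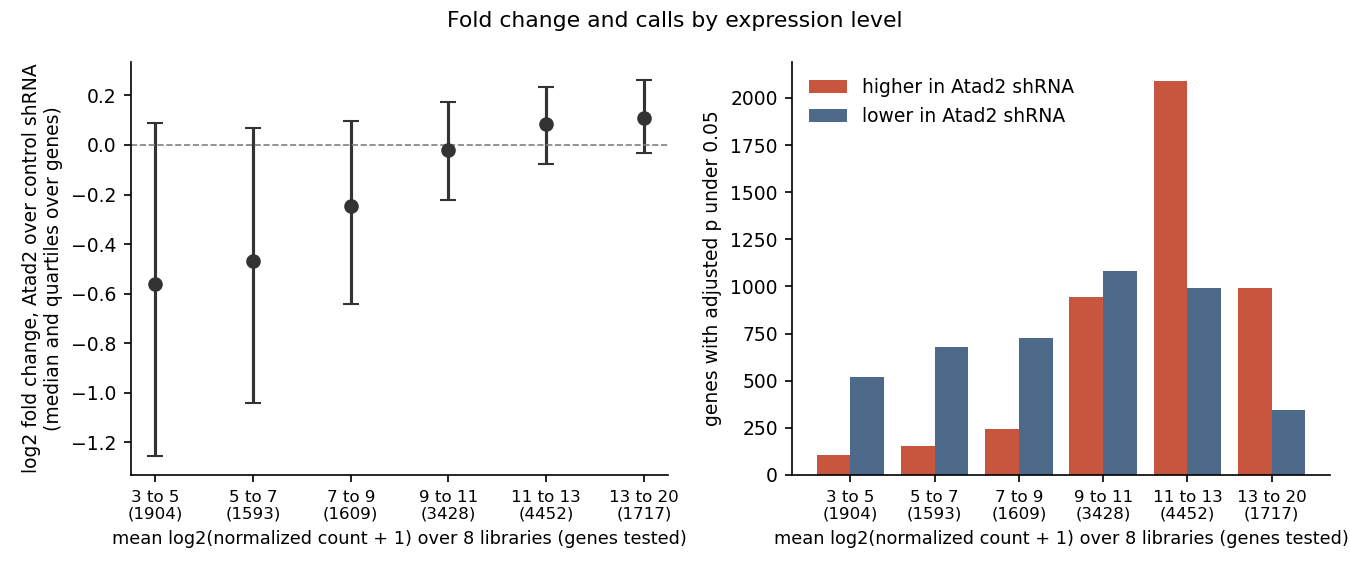
Left, median and quartiles of the log2 fold change (Atad2 over control shRNA) of genes in 6 bands of mean log2 level; right, the number of genes higher and lower at a limma adjusted p under 0.05 in each band. The median goes from -0.56 in the weakest band to 0.11 in the strongest, and higher genes outnumber lower ones only above a mean of 11.

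Muscle differentiation genes went in both directions, which bears on the myogenesis named in the series title. Among 30 measured of 45 sarcomere and contractile genes, 18 rose, 3 fell and 9 did not pass, with the same counts adjusted over the list alone. Of these, 17 rose at least 2-fold, and the list's median log2 fold change was 1.58. Ttn rose from 8.07 ± 0.08 to 12.07 ± 0.14. Myh3 (embryonic myosin heavy chain) rose by 5.44 ± 0.43, from 1 to 9 reads per control library to 113 to 235. Measured here means a mean above 3 over all 8 libraries. Myh3, at 2.14 in the controls, passed only through the Atad2 libraries, and genes weak in both groups were left out. The list's counts and median hold only for genes that passed this filter. Mylpf (a fast-muscle myosin light chain) rose by 2.83 ± 0.25 and Tnnt2 (troponin T) by 2.48 ± 0.13. The tropomyosin genes Tpm1 and Tpm2, which are also used outside muscle, changed by -0.49 ± 0.03 and -0.60 ± 0.03. The list was higher than other genes by camera with a preset correlation (adjusted p = 0.0025), with adjusted p = 0.489 with an estimated correlation. With genes above a mean log2 level of 5 alone, 8 of its genes rose and that camera adjusted p was 0.27, in a range of 0.000207 to 0.27 over the alternatives.

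The myogenic regulators were a mixed group: 11 of 22 measured genes rose, 5 fell and 6 did not pass, again with the same counts adjusted over the list alone (camera adjusted p = 0.14). Myod1, a determination factor of the muscle lineage, rose by 0.25 ± 0.04 to 12.86 ± 0.06, and Myog (myogenin), which acts early in differentiation, rose from 4.79 ± 0.26 to 6.94 ± 0.33 (2.15 ± 0.26, limma adjusted p = 3.3e-07). Myog stayed weak, at 73 to 158 reads per Atad2 library. Myf5, another determination factor, fell by 1.28 on the log2 scale, to 8.26 ± 0.13. The differentiation inhibitors Id1 and Id2 rose by 0.88 ± 0.04 and 0.90 ± 0.04, the homeobox gene Six4 by 0.75 ± 0.04 and Snai1 by 0.82 ± 0.05, while Tead1 changed by -0.34 ± 0.03.

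Of 20 measured satellite cell and myoblast identity genes, 11 fell, 7 rose and 2 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.62). Pax7, the transcription factor of muscle stem cells, fell from 19 to 41 reads per control library to 0 to 12 (-3.27 ± 0.70, limma adjusted p = 0.00040). Cdh15 (M-cadherin) changed by -0.96 ± 0.05, the proteoglycan gene Sdc4 by -1.13 ± 0.04, Cd34 by -1.93 ± 0.13 and Rgs2 by -0.99 ± 0.12. Met, the receptor for hepatocyte growth factor, and Sdc3 rose by 1.19 ± 0.03 and 1.27 ± 0.03.

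In the list of excitation-contraction coupling, neuromuscular junction and muscle metabolism genes, 14 of 25 measured members rose, 4 fell and 7 did not pass (camera adjusted p = 0.32). Musk, the receptor kinase of the neuromuscular junction, rose by 0.73 ± 0.04, the calcium channel subunit gene Cacng1 by 0.58 ± 0.04, the calcium release channel gene Ryr1 by 1.92 ± 0.16 and the calcium pump gene Atp2a1 by 2.04 ± 0.25. Jph2 and the muscle enolase gene Eno3 changed by -0.74 ± 0.04 and -0.53 ± 0.04. Without control replicate 4, 9 members of this list rose. Among 20 measured fusion genes, 7 rose, 10 fell and 3 did not pass (camera adjusted p = 0.49). Tmem8c, the older symbol of the fusogen gene Mymk, rose from 4.32 ± 0.26 to 7.20 ± 0.08 (2.88 ± 0.25), and the integrin gene Itgb1 by 0.38 ± 0.04. Elmo1 fell from 108 to 145 reads per control library to 0 to 5, Anxa5 changed by -0.28 ± 0.03 and Bin3 by -0.42 ± 0.06. In both lists the counts adjusted over the list alone were the same.

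**Figure D3:**
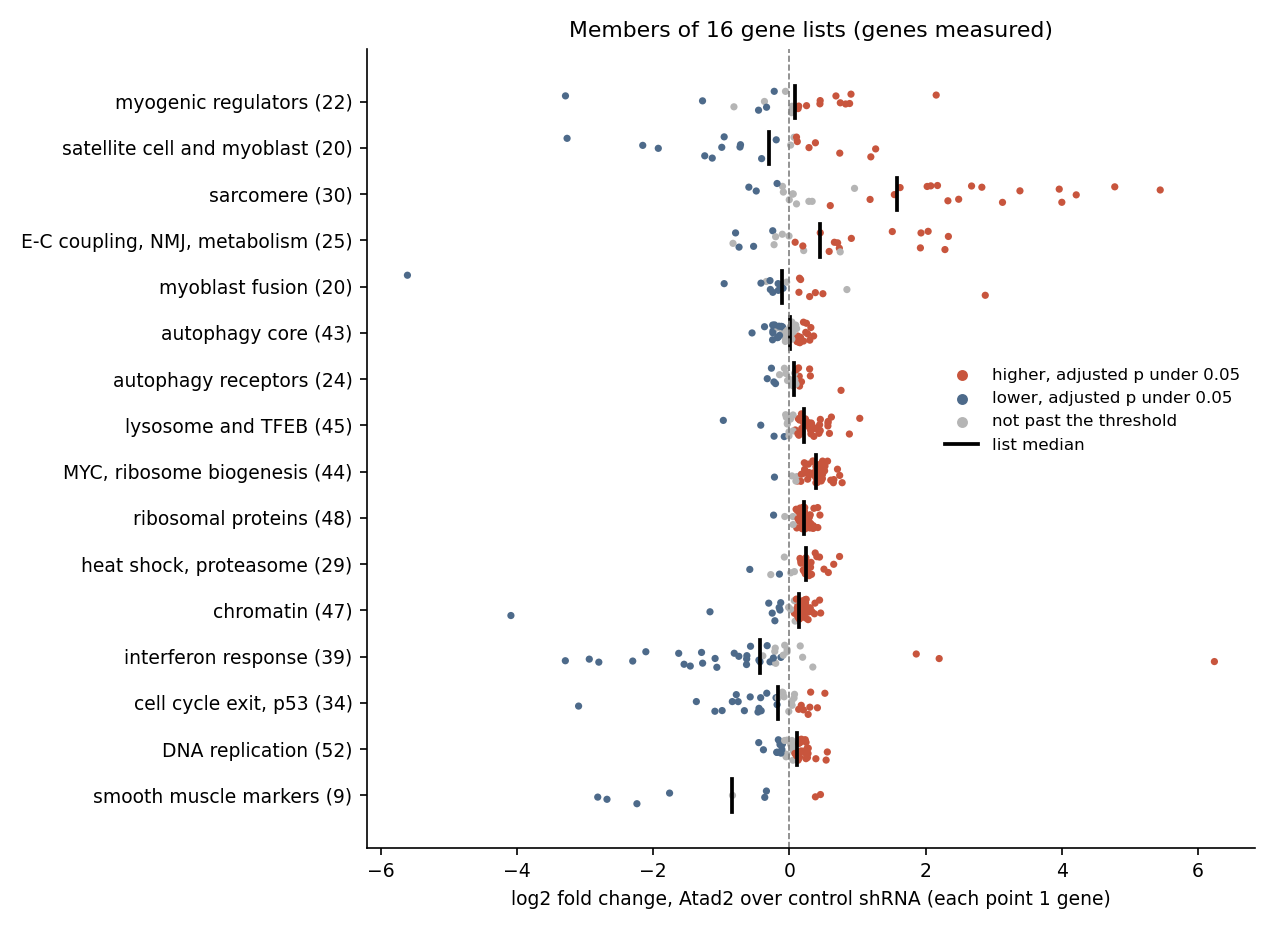
Log2 fold change (Atad2 over control shRNA) of each measured member of 16 gene lists, coloured by direction where the limma adjusted p is under 0.05, with the median of each list as a black line. The sarcomere list has a median of 1.58, the interferon list one of -0.43, and the 43 autophagy core genes lie around 0.

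The autophagy machinery itself moved little and in both directions. Of 43 measured core autophagy genes, 14 rose, 13 fell and 16 did not pass, none by 2-fold or more, with the same counts adjusted over the list alone. The list's median log2 fold change was 0.0013 and its mean -0.0084, so their signs differ (camera adjusted p = 0.90). Ulk1, the kinase that starts autophagy, rose by 0.21 ± 0.04, Atg2b by 0.35 ± 0.03, Wdr45b by 0.30 ± 0.05 and Gabarapl1 by 0.25 ± 0.04. Map1lc3b, which encodes the autophagosome marker LC3B, stood at 12.16 ± 0.08 and 12.31 ± 0.02 (0.15 ± 0.04, limma adjusted p = 0.0027). Its paralog Map1lc3a changed by -0.55 ± 0.07 and the fusion SNARE gene Stx17 by -0.37 ± 0.05. Becn1 (beclin 1) stood at 11.88 ± 0.09 and 11.73 ± 0.11, with overlapping values (-0.15 ± 0.05, limma adjusted p = 0.016). The Map1lc3b call was lost with quantile (limma adjusted p = 0.187) and cyclic loess normalization (0.174; range 0.000502 to 0.187). That of Becn1 was lost without the variance trend (0.0927) and without control replicate 2 (0.0569), control replicate 4 (0.0541) or Atad2 replicate 4 (0.0652; limma adjusted p range 0.000769 to 0.0927). With quantile normalization 9 core genes rose and 15 fell, and without control replicate 4, 9 rose.

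Sqstm1, the gene of the autophagy receptor p62, rose from 15.88 ± 0.10 to 16.64 ± 0.03 (0.76 ± 0.04, limma adjusted p = 9.4e-13), at 78591 to 114170 reads per Atad2 library. Of 24 measured autophagy receptor and mitophagy genes, 8 rose, 4 fell and 12 did not pass (camera adjusted p = 0.51). With quantile normalization, 5 of them rose and 10 fell. The mitophagy genes Phb2, Fundc1 and Bcl2l13 rose by 0.31 ± 0.03, 0.30 ± 0.06 and 0.18 ± 0.04, while Rtn3 changed by -0.23 ± 0.03 and Fam134b by -0.20 ± 0.04.

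Among lysosomal genes, 32 of 45 measured members of the lysosome and TFEB list rose, 4 fell and 9 did not pass, with the same counts adjusted over the list alone. The median log2 fold change was 0.21. Atp6v1b2, a subunit of the lysosomal proton pump, rose by 1.03 ± 0.04, Ctsd (cathepsin D) by 0.88 ± 0.03, Psap (prosaposin) by 0.59 ± 0.03, the cholesterol transporter gene Npc1 by 0.57 ± 0.03, and Lamp1, of the lysosomal membrane, by 0.33 ± 0.03. Tfeb, a transcription factor for these genes, rose by 0.31 ± 0.08. Sgsh and Rragd changed by -0.97 ± 0.07 and -0.42 ± 0.06. The list was higher than other genes by camera (adjusted p = 6.6e-06), with adjusted p = 0.561 with an estimated correlation. With quantile normalization, 24 of its members rose and 9 fell.

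Genes of ribosome production rose in the Atad2 libraries. Of 44 measured MYC target and ribosome biogenesis genes, 40 rose, 1 fell and 3 did not pass, and 41 rose and 1 fell adjusted over the list alone. The median log2 fold change was 0.40 (camera adjusted p = 8.9e-13, and adjusted p = 0.489 with an estimated correlation). Nhp2 and Gnl3, of the nucleolus, rose by 0.70 ± 0.04 and 0.77 ± 0.05, the spermidine synthase gene Srm by 0.74 ± 0.05 and Cad, of pyrimidine synthesis, by 0.48 ± 0.03. The member that fell was Mxd1, a MYC antagonist (-0.22 ± 0.09, limma adjusted p = 0.047), and its call was lost under 11 of 20 alternatives (limma adjusted p from 0.0168 to 0.664), among them leaving out control replicate 1, 3 or 4 or Atad2 replicate 1, 2 or 3 (0.0623 to 0.155).

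Of 48 measured cytoplasmic ribosomal protein genes, 44 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone. Their median log2 fold change was 0.22 (camera adjusted p = 2.7e-10, and adjusted p = 0.566 with an estimated correlation). Rpl13a, Rpl8, Rpl11 and Rpl15 rose by 0.36 to 0.45, and Rps28 changed by -0.23 ± 0.03. With quantile normalization 4 of these genes fell, and without control replicate 2, 2 fell. Ribosomal protein genes have many processed copies, so reads may be split among them. In the heat shock and proteasome list, 23 of 29 genes rose, 2 fell and 4 did not pass, and 23 rose and 3 fell adjusted over the list alone. The median was 0.24 (camera adjusted p = 2.0e-05, and adjusted p = 0.566 with an estimated correlation). The proteasome genes Psmb6, Psmd11 and Psma7 rose by 0.74 ± 0.04, 0.65 ± 0.04 and 0.40 ± 0.04, the co-chaperone gene Bag3 by 0.57 ± 0.04, and the small heat shock gene Hspb1 changed by -0.58 ± 0.06.

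Among 47 chromatin, histone chaperone and ATAD2-related genes, 35 rose, 8 fell and 4 did not pass, and 36 rose and 8 fell adjusted over the list alone (median 0.15). The methyltransferase gene Kmt2d rose by 0.46 ± 0.03, the acetyltransferase genes Kat2a and Ep300 by 0.44 ± 0.04 and 0.33 ± 0.03, and the histone chaperone gene Ubn1 by 0.38 ± 0.03. The estrogen receptor gene Esr1 changed by -1.17 ± 0.08. The camera adjusted p of this list was 0.0020, and adjusted p = 0.489 with an estimated correlation. With quantile normalization 20 members rose and 9 fell, and the camera adjusted p was 0.23, in a range of 1.74e-05 to 0.242 over the alternatives.

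Of 52 DNA replication genes, 28 rose, 10 fell and 14 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.074). The licensing factor genes Cdt1 and Mcm7 rose by 0.56 ± 0.04 and 0.54 ± 0.04, Pcna by 0.39 ± 0.03 and Dnmt1 by 0.25 ± 0.03, while E2f7 and Tyms changed by -0.45 ± 0.04 and -0.38 ± 0.04. With quantile normalization, 16 rose and 16 fell. Without control replicate 2 that camera adjusted p was 0.0429 (range 0.00606 to 0.791), and 6 fell without control replicate 1 and 5 without Atad2 replicate 3. Of 50 mitosis genes, 16 rose, 11 fell and 23 did not pass, and 16 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.81). With quantile normalization, 4 of the mitosis genes rose and 22 fell, and the list was lower than other genes (camera adjusted p = 0.0106, range 0.0106 to 0.987). Of 34 cell cycle exit and p53 target genes, 17 fell, 8 rose and 9 did not pass, and 18 fell and 8 rose adjusted over the list alone (camera adjusted p = 0.074, and 0.0275 with quantile normalization in a range of 0.0275 to 0.0953). Ccng1 changed by -0.84 ± 0.04, Phlda3 by -0.75 ± 0.04, Eda2r by -0.78 ± 0.05 and Btg2 by -1.10 ± 0.09. Trp53 itself, which encodes p53, rose by 0.31 ± 0.04, and Rbl2 by 0.41 ± 0.04.

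Interferon response genes were mostly lower after the knockdown. Of 39 measured members, 25 fell, 3 rose and 11 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was -0.43 (camera adjusted p = 0.00018, and adjusted p = 0.489 with an estimated correlation). Ifit2 changed by -1.07 ± 0.07, Gbp7, a guanylate-binding protein gene, by -3.29 ± 0.27, and the class I histocompatibility gene H2-D1 by -0.63 ± 0.05. H2-D1 has close relatives, so its own share of the reads is uncertain. Oasl1 rose from 3.38 ± 0.47 to 5.58 ± 0.45. With quantile normalization 6 of these genes rose. Some members were weakly expressed, and the list was not compared with genes of matched level. Of all genes, 522 of 1904 were lower at a mean log2 level of 3 to 5 and 681 of 1593 at 5 to 7. At 7 to 9, 728 of 1609 genes were lower, and at 9 to 11, 1081 of 3428. The chemokine gene Ccl5 had 0 reads in each control library and 48 to 105 reads in each Atad2 library, at least 26.0-fold higher against a floor of 3 reads per control library. The list's median with Ccl5 at that bound was -0.43, a value that a single gene far above it cannot move.

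In the unfolded protein and integrated stress response list, 17 of 34 measured genes fell, 13 rose and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.51). The stress-induced regulator genes Ddit3 and Atf5 changed by -1.14 ± 0.05 and -0.84 ± 0.04, Chac1 by -1.28 ± 0.09 and Cebpg by -0.65 ± 0.05. Slc7a11, in the same list, rose from 9.17 ± 0.15 to 12.58 ± 0.20, and Cebpb rose by 0.85 ± 0.06. Of 37 measured extracellular matrix genes, 19 fell, 13 rose and 5 did not pass, and 20 fell and 13 rose adjusted over the list alone (camera adjusted p = 0.21, and 0.0442 with quantile normalization in a range of 0.0442 to 0.397). Thbs1 (thrombospondin 1) changed by -1.49 ± 0.05, Ctgf by -2.70 ± 0.11, the crosslinking enzyme gene Lox by -0.66 ± 0.04 and the protease gene Mmp2 by -2.11 ± 0.13. Timp1, a protease inhibitor gene, and Nid1 rose by 0.88 ± 0.04 and 0.53 ± 0.03.

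Markers used for 7 other cell types did not move in one direction. Des and Cd34, among these markers, are also in the satellite cell and myoblast list, so such markers need not come from other cells. Of 9 measured smooth muscle and pericyte markers, 6 fell, 2 rose and 1 did not pass (median -0.84, camera adjusted p = 0.016, and adjusted p = 0.489 with an estimated correlation). Without the variance trend that camera adjusted p was 0.058, in a range of 0.0106 to 0.058. Acta2, smooth muscle actin, fell from 17.32 ± 0.08 to 15.07 ± 0.10, Tagln changed by -2.68 ± 0.07, Mcam by -1.76 ± 0.12 and Smtn by -0.34 ± 0.04. Des (desmin) and Cspg4 rose by 0.38 ± 0.03 and 0.46 ± 0.04. Of 5 measured fibroblast markers 3 fell and 1 rose, of 6 adipocyte markers 5 fell and 1 rose, and of 5 osteoblast and chondrocyte markers 3 rose. Of 4 endothelial markers 1 fell, of 4 macrophage markers 1 rose, and of 5 neural markers 2 rose and 1 fell. Without Atad2 replicate 1, 2 endothelial markers fell, and 1 neural marker rose and 2 fell, and without Atad2 replicate 2, 2 endothelial markers fell. The camera adjusted p-values of these last 6 lists were 0.21, 0.21, 0.089, 0.46, 0.72 and 0.90. Counts adjusted over the list alone were the same in the 7 marker lists.

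The remaining lists fixed in advance did not pass camera. In the FoxO, mTOR and atrophy list 11 of 34 measured genes rose and 12 fell (13 and 13 adjusted over the list alone, camera adjusted p = 0.90), and in the inflammatory list 9 of 21 rose and 6 fell (9 and 7 adjusted over the list alone, adjusted p = 0.73). Of 41 nuclear oxidative phosphorylation genes 14 rose and 7 fell, but 5 rose and 15 fell with quantile normalization (camera adjusted p = 0.64). Of 34 glycolysis and hypoxia genes 10 rose and 12 fell (camera adjusted p = 0.62), and 5 rose with quantile normalization. Of 33 cholesterol and fatty acid synthesis genes 8 rose and 16 fell (camera adjusted p = 0.46, and 0.027 with quantile normalization in a range of 0.027 to 0.593). Of 42 genes of TGF-beta, BMP, Notch and Wnt signalling 15 rose and 17 fell (15 and 18 adjusted over the list alone, camera adjusted p = 0.73). Of 25 immediate early genes 11 rose and 8 fell (camera adjusted p = 0.32), and of 30 replication-dependent histone genes, whose near-identical copies share reads, 4 rose and 8 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.49). With quantile normalization 0 histone genes rose and 16 fell by limma (camera adjusted p = 0.0134, range 0.0134 to 0.736), and without control replicate 4 or Atad2 replicate 3, 5 fell. The oxidative phosphorylation, glycolysis, cholesterol and immediate early lists kept their counts when adjusted over the list alone. In the inflammatory, oxidative phosphorylation, glycolysis, cholesterol, FoxO and neural lists the median and the mean log2 fold change differed in sign (0.11 and -0.11, 0.036 and -0.033, 0.015 and -0.090, -0.053 and 0.0083, -0.016 and 0.041, 0.11 and -0.31). The direction of camera followed the mean in the glycolysis list and in the autophagy core list, and the median in the other 5.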

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

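The values below stood apart from the other 3 libraries of their group, for genes named by the rule or, for H19, Cck and Prlr, chosen after their values were seen, and Ephx1 belongs to a list written after the largest changes were seen; no cause was tested for them. In each case the gap from the highest or lowest library to its nearest neighbour took up most of the range of its group of 4. This held for 29 of 434 groups of values screened (6.68%), over 214 genes and 3 measures of depth, where chance gives about 1 in 20 (21.7). Control replicate 3 held 8 of the 29 and Atad2 replicate 4 held 6. All levels are log2(normalized count + 1), with the range of the other 3 libraries in parentheses.

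In control replicate 3, Slco4a1 lay at 10.46 (10.672 to 10.693), Snai1 at 11.275 (11.401 to 11.426), Ep300 at 14.191 (14.092 to 14.106), Cox8a at 12.778 (12.836 to 12.844), Mvk at 10.581 (10.708 to 10.715), Insig1 at 12.057 (12.213 to 12.221), Dusp1 at 12.032 (12.181 to 12.206) and Hist1h1a at 13.817 (13.944 to 13.948). In control replicate 2, Clec4d lay at 2.329 (3.486 to 3.619), Rorb at 9.571 (9.043 to 9.116), Atg2b at 12.619 (12.673 to 12.679), Tgfb1 at 12.797 (12.855 to 12.863) and Ephx1 at 14.2 (14.306 to 14.324). In control replicate 1, Sp7 lay at 0.956 (3.708 to 4.068) and Dnmt1 at 14.244 (14.196 to 14.2).

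In Atad2 replicate 4, Becn1 lay at 11.562 (11.769 to 11.804), Ly6a at 11.875 (11.092 to 11.17), Ep300 at 14.401 (14.465 to 14.476), Cxcl5 at 9.578 (8.869 to 8.908), Insig1 at 11.926 (11.732 to 11.742) and H19 at 11.508 (10.82 to 10.901). In Atad2 replicate 3, Tpsab1 lay at 5.879 (6.46 to 6.565), Stx17 at 10.757 (10.933 to 10.953), Esr1 at 8.566 (8.749 to 8.784) and Atp5a1 at 15.109 (15.142 to 15.146). In Atad2 replicate 2, Aurkb lay at 12.916 (12.983 to 12.993) and Psma7 at 13.325 (13.188 to 13.205). In Atad2 replicate 1, Cck lay at 2.218 and Prlr at 0.936, where the other 3 Atad2 libraries had no reads of either gene.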

How the results depend on the processing

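Cyclic loess, limma-voom and thinning to equal depth were chosen only after the data were seen. Counting all calls, 4107 to 4662 genes were higher and 3861 to 4717 lower across settings at the same threshold. Leaving out a library gave 4254 to 4573 and 4039 to 4401, an adjusted p under 0.01 gave 3805 and 3480, and a 2-fold minimum left 370 and 1265. Of the original calls, 3556 higher and 3360 lower genes were called the same way with quantile normalization, and 2 calls reversed. Atad2 stayed between -2.84 and -2.68. Of 4248 recomputed values of other named genes, 36 lost their call and 0 turned direction by limma. With the replicate block, 4562 genes were higher and 4379 lower (4490 and 4289 shared). Same-numbered libraries did not deviate together (correlations 0.0336, -0.0227, 0.0208 and 0.0113), which gave no sign of pairing by number but cannot exclude it. Of all genes above a mean log2 level of 9, 41.9% were higher in the main fit, 33.3% with quantile normalization and 32.6% with cyclic loess. For the lists, camera adjusted p-values on the other side of the threshold follow, and the cause was not tested. Quantile normalization and cyclic loess gave 0.0106 and 0.0134 for mitosis, whose direction turned to lower, 0.0275 and 0.028 for p53 targets, 0.23 and 0.242 for chromatin, 0.027 and 0.028 for cholesterol synthesis, 0.0442 and 0.047 for extracellular matrix, and 0.0134 in both for histones. DNA replication passed without a filter (0.00606) and without control replicate 2 (leave-one-out range 0.0429 to 0.133). The sarcomere list did not pass above a mean of 5 (0.27, with fewer genes), nor smooth muscle without the trend (0.058). With an estimated correlation the values were 0.489 for smooth muscle, sarcomere, MYC, chromatin and interferon, 0.561 for lysosome and 0.566 for heat shock and ribosomal proteins. By fry, which does not compare a list with other genes, these lists passed too: adipocyte 0.00596, osteoblast 2.33e-05, endothelial 0.000462, macrophage 0.0245, myogenic 2.33e-05, excitation-contraction 0.000266, autophagy receptors 0.00613, DNA replication 0.00596, p53 2.33e-05, stress response 0.0241, extracellular matrix 0.0484 and immediate early 0.0199. Of 724 recomputed list values, 688 kept their side of the threshold, among which 17 changed sign without passing. Of 1316 recomputed member counts, 64 moved by over 1.5 times, 18 of them with quantile normalization. Depth limited statements on genes near the floor of 3 reads.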

Other observations

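The tests of other splits, of unequal depth, of a wrong size factor, of background as the whole cause, of the lysosome list and of list shares under other scalings were chosen only after their results were seen, and so was the use of a gene span in the background estimate. The 8 libraries allow 35 splits into 4 and 4. In 1 of 35 splits, the real one, limma called as many as 4528 genes higher, and likewise in 1 of 35 as many as 4352 lower. That is the smallest share that 35 splits can give. It argues against a chance split of these 8 libraries as the source of the calls, without excluding it. Chance between cultures, which the labels do not tell apart, was not addressed. The highest other split gave 0 in each direction by limma, with 49 to 1434 genes at an unadjusted p under 0.05 against 9384 in the real split. A real difference widens the spread within the other splits, which lowers their counts.

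Weakly expressed genes were mostly lower after the knockdown: 83.3% of calls at a mean log2 level of 3 to 5. Unequal depth is argued against, since after thinning to equal depth 83.1% of those calls (493 of 593) were lower. A wrong size factor for a group would shift all levels alike, but the median above 13 exceeded that at 3 to 5 by 0.671 (bootstrap interval 0.632 to 0.723). More background such as genomic DNA in the controls remains a candidate explanation for a part: olfactory, vomeronasal and other silent families (1588 genes, 104 with reads) had 2.12 times more RPM in the controls (5.97 ± 0.234 against 2.82 ± 0.465, SD, n = 4 each, exact permutation p = 0.0286), yet per kb of exon or gene span that excess would give 2.67% of the loss (2.61 to 2.79 without any 1 library). Dropped multi-mapped reads would understate this share, a change of expression by the knockdown stays open, and of the silent genes Vmn2r79 alone had 240 control reads against 1.

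Changes of 4-fold or more were seen in 122 higher and 325 lower genes, and 8 genes went from at least 100 reads in every control library to at most 10 in every Atad2 library, while Myh3 went the other way. They were Dkk3, Lgalsl and Elmo1, named by the rule, and Cck, Prlr, Prss35, Hykk and Hs3st1, chosen after their values were seen. If the shRNA populations were sublines with different chromosome numbers, chromosome medians would differ, but the largest distance from the median of all genes was 0.0837, on chromosome 15, beyond the 0.0465 of shuffled genes but small beside the shift that a copy gained or lost in most cells would give. The 10 nearest expressed genes of a gene changed 4-fold moved with it by a median of 0.0326 (0.0219 to 0.0451, 436 genes). The quartiles were -0.043 and 0.093, so the typical shift was small, though in the direction of the changed gene. This argues against gained or lost segments as the source of most of these changes. A median cannot exclude such segments for a minority of the genes, which stays open. A difference between cell populations without copy-number change, and a response to Atad2 loss, may each explain these changes and stay open. The labels name no other shRNA against Atad2, so a response to Atad2 loss cannot be told apart from other effects of this shRNA.

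Sqstm1 is a target of the oxidative stress factor NRF2, which led to a list of NRF2 targets written after the largest changes were seen, without Sqstm1, Slc7a11 and other genes already seen. Of 24 measured members 83.3% rose (20 higher, 3 lower, median 0.97), among them Gsta4 (2.12 ± 0.04), Txnrd1 (1.76 ± 0.04), Gclm (1.72 ± 0.04), Nqo1 (1.16 ± 0.03) and Hmox1 (0.83 ± 0.06), against 41.9% of all genes above a mean of 9, and 20 rose with quantile normalization too, while Ephx1 fell by 0.47 on the log2 scale. That 41.9% is not matched for level: 992 of 1717 genes above a mean of 13 and 2089 of 4452 at 11 to 13 were higher. Most of the NRF2 members lay above 13. For the NRF2 list, limma's camera gave an adjusted p of 2.0e-12, and 0.434 with an estimated correlation. The lysosome list, which TFEB can drive, had 71.1% of members higher against the same 41.9%, but 53.3% against 33.3% with quantile normalization and a camera adjusted p of 0.561 with an estimated correlation, so whether that programme takes part stays open. NRF2 may contribute to the rise of Sqstm1, as a hypothesis; stress from transfection or from the shRNA itself was not tested and stays open.

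Igf2 and H19, imprinted neighbours on chromosome 7, went in opposite directions: Igf2 rose from 6.67 ± 0.33 to 10.68 ± 0.10, and H19 fell from 14.34 ± 0.14 to 11.03 ± 0.32 (log2 fold change -3.31 ± 0.10, limma adjusted p = 1.6e-16). H19, Gsta1 (3.06 ± 0.13), Aldh3a1 (2.89 ± 0.04), Cyp1a1 (3.04 ± 0.16) and Nfe2l2, the gene of NRF2 (0.34 ± 0.03), were chosen after their values were seen. The skeletal and cardiac actin genes Acta1 and Actc1 did not pass (-0.09 ± 0.12, limma adjusted p = 0.535, and -0.0033 ± 0.49, adjusted p = 0.996), unlike most measured sarcomere genes.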
